A study of Mus musculus with 12 samples.

How the data were processed

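Polyadenylated RNA of mouse G1E-ER4 cells was sequenced in 12 libraries, 3 for each of 4 groups, after 24 h of culture with 100 nM β-estradiol. Groups and replicate numbers were taken from the sample titles and treatment tags. For the ALAD group the treatment protocol names 50 µM DFO and the titles name 0.2 mM SA; the titles were followed. RNA was isolated with a spin column kit and strand-specific mRNA libraries were made, per the labels' protocols. Per the submitters' processing notes, the tools used were Trimmomatic 0.33, FastQC, HISAT2 2.1.0, featureCounts and edgeR, with the mouse genome build mm10; their settings and the annotation release are not given in the sources used here. The authors deposited 1 table of TPM values per library, with a gene symbol in each of 55487 rows.

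Of these rows, 234 carried 1 of 114 symbols that occur more than once, and the copy with the highest mean kept the symbol. Hbb-b1, Hbb-b2, Ahsp and Fdx1l were not found under those symbols. Gene positions and exon lengths came from the GENCODE M21 annotation of the same build, in which 95.8% of rows had a symbol that is unique (53170 rows with an exon length). TPM keeps no total count, but TPM multiplied by exon length fell on whole multiples of a step for each library. For values of up to 200 reads, between 98.8% and 99.0% came out whole within 0.1 read. The recovered totals were between 19857421 and 24326304 reads per library. Replicates of a group differed beyond sampling noise in every pair (chi-square per degree of freedom between 2.03 and 5.62), no pair held identical values, and each library counted as 1 replicate.

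Genes with at least 1 TPM in at least 3 libraries were tested (11920). Values were taken as log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3 over all 12 libraries, with 1 mean per group, no covariate and a mean-variance trend in the empirical Bayes step. Each treatment was compared with control and with each other treatment, and p-values were adjusted by Benjamini and Hochberg over the tested genes of a comparison, with 0.05 as the threshold. Fold changes given as multiples are ratios of group mean TPM. Tables were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were made with matplotlib 3.10.9. The fit was tested on simulated data with 200 changed genes per treatment among 11920: at 1.2-fold it recovered 66%, 68% and 40%, at 1.5-fold 92%, 96% and 94%, at 2-fold 92%, 98% and 100% and at 4-fold 100%, 98% and 100% for DTPA, DFO and SA, and it called 0.0853%, 0.102% and 0.0939% of the 11720 unchanged genes. Each recovery rests on 50 genes drawn at random. Means and spread were the same for all treatments, so differences in recovery between treatments come from the draw. The changed genes were drawn only from those above 5 TPM in control, so recovery of lower genes was not tested. Rises and falls were equal in number and the noise was independent between genes. The rate of false calls therefore does not carry over to comparisons in which many more genes are called.

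Before the data were examined, 21 gene lists, the tests and the alternatives below were fixed. The lists cover zinc importers, zinc exporters, metallothioneins with MTF1, iron uptake and storage, heme synthesis, globins, erythroid maturation, progenitor genes repressed by GATA1, ATF4, hypoxia-inducible, BACH1 and NRF2 and p53 targets, S phase, mitosis, cholesterol synthesis, iron-sulfur cluster assembly, endoplasmic reticulum chaperones, autophagy, and markers of megakaryocytes, of mast and myeloid cells and of lymphoid cells. Each list was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the 20 lists with more than 1 measured member. The fry test, which asks whether a list moves without reference to other genes, was an alternative. The genes named were the 10 largest rises and falls per treatment among called genes whose treated libraries all lay outside the control range with a mean of at least 5 TPM in either group, up to 4 called members per list with a mean of at least 1 TPM, the 5 highest of each treatment in a pair, and always Slc39a10, Mt1, Mt2, Slc30a1, Tfrc, Alas2, Alad, Hmox1, Hba-a1 and Hbb-bt. Predicted gene models were not named, some names were left out for length, and some results that the rule gives are not reported here.

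The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, median-of-ratios scaling, trimmed-mean scaling (30% of ratios and 5% of means trimmed at each end), removal of the globin genes, a robust empirical Bayes step, a fit of only the 6 libraries compared, the replicate number as a block, each library left out in turn, and a threshold of 1 on the absolute log2 fold change. Limma's voom on the recovered reads (at least 10 reads in 3 libraries), a rescaling to protein-coding genes only, and correlations without each control library were added after the data were seen. Unchanged groups against shared controls were simulated from the residual spread of each gene, 100 times for correlations and 20 times for shared calls.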

Results

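RNA was sequenced from G1E-ER4 cells, a mouse erythroid progenitor line that lacks its own functional Gata1 gene and carries GATA1 fused to an estrogen receptor domain, so that estradiol starts red cell maturation. All cultures received 100 nM β-estradiol, and the libraries were made 24 h later. The 4 groups held 3 libraries each: control cells, cells given 50 µM DTPA (a chelator used here to lower zinc), cells given 50 µM DFO (an iron chelator), and cells given 0.2 mM SA, a treatment used to inhibit ALAD and so lower protoporphyrin. The treatment protocol and the sample titles give different agents for the ALAD group, and the titles, which say SA, were followed. Values are TPM, transcript abundances scaled to a fixed total per library, as deposited. Log2 fold changes are differences of log2(TPM + 1), which understate the change of genes near 1 TPM. Changes given as multiples are plain ratios of group mean TPM. These can rest on few reads where a mean is near or below 1 TPM, the fewer the shorter the exons. The labels call the 3 libraries of each group biological replicates, so the p-values measure the spread between those replicates and nothing wider.

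Depth was similar across libraries. The spacing of low TPM values corresponded to between 19857421 and 24326304 reads on genes per library, and 1 read per kilobase of exon was worth between 0.124 and 0.160 TPM. Globin genes held 3.70% ± 0.274 of all TPM in control (SD, n = 3), 5.34% ± 0.486 with DTPA, 2.50% ± 0.0489 with DFO and 2.05% ± 0.114 with SA. Ribosomal protein genes held 8.62% ± 0.124, 12.3% ± 0.281, 9.52% ± 0.0642 and 10.1% ± 0.118 in the same order, mitochondrially encoded genes 6.33% ± 0.119, 7.45% ± 0.113, 6.28% ± 0.102 and 6.46% ± 0.0680, and genes under 200 bp 2.68% ± 0.472, 3.57% ± 0.228, 1.98% ± 0.126 and 2.13% ± 0.122. What moved these shares was not tested. Because TPM sums to the same total in every library, such shifts move the values of all other genes. The first principal component of the 11920 tested genes held 61.4% of the variance, and the second 6.55%.

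The comparison of DTPA with control asked how maturing erythroid cells respond to low zinc. The metallothioneins, small zinc-binding proteins whose genes are driven by the zinc-sensing factor MTF1, fell steeply. Mt2 fell from 2519 ± 83.7 TPM to 9.82 ± 1.26 TPM (mean ± SD, n = 3 each), a log2 fold change of -7.87 (SE 0.0796, adjusted p = 2.13e-14). Mt1 fell 15.3-fold, from 1872 ± 71.4 to 122 ± 3.52 TPM (adjusted p = 2.22e-15). Slc39a10, which encodes the plasma membrane zinc importer ZIP10 named in the series title, rose 11.8-fold from 1.58 ± 0.0799 to 18.7 ± 0.688 TPM (log2 fold change 2.93, adjusted p = 5.01e-10).

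Slc30a1, which encodes the zinc exporter ZnT1, rose from 39.0 ± 2.26 to 73.7 ± 3.45 TPM (log2 fold change 0.90, adjusted p = 4.76e-08). Among 9 measured ZIP importers, 2 rose (Slc39a10 and Slc39a1), 2 fell (Slc39a3 and Slc39a8) and 5 did not pass. Under median-of-ratios scaling the importers split 5 higher and 2 lower. Neither importers (adjusted p = 0.275 by camera) nor the 6 measured ZnT exporters (3 rose and 3 fell, adjusted p = 0.781) stood apart from other genes. The exporters had a median log2 fold change of -0.165 and a mean of -0.043 while camera gave the direction up. All 3 measured members of the metallothionein and MTF1 list fell (adjusted p = 0.00456), Mtf1 itself from 23.7 ± 0.681 to 16.3 ± 0.535 TPM. On the mouse genome build GRCm38 (mm10), Slc39a10 lies on chromosome 1 from 46807544 to 46892852, Slc30a1 on chromosome 1 from 191906767 to 191913247, Mt2 on chromosome 8 from 94172664 to 94173568 and Mt1 next to it from 94179082 to 94180327. All 4 are protein-coding genes, and the values count reads over their exons.

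**Figure D1:**
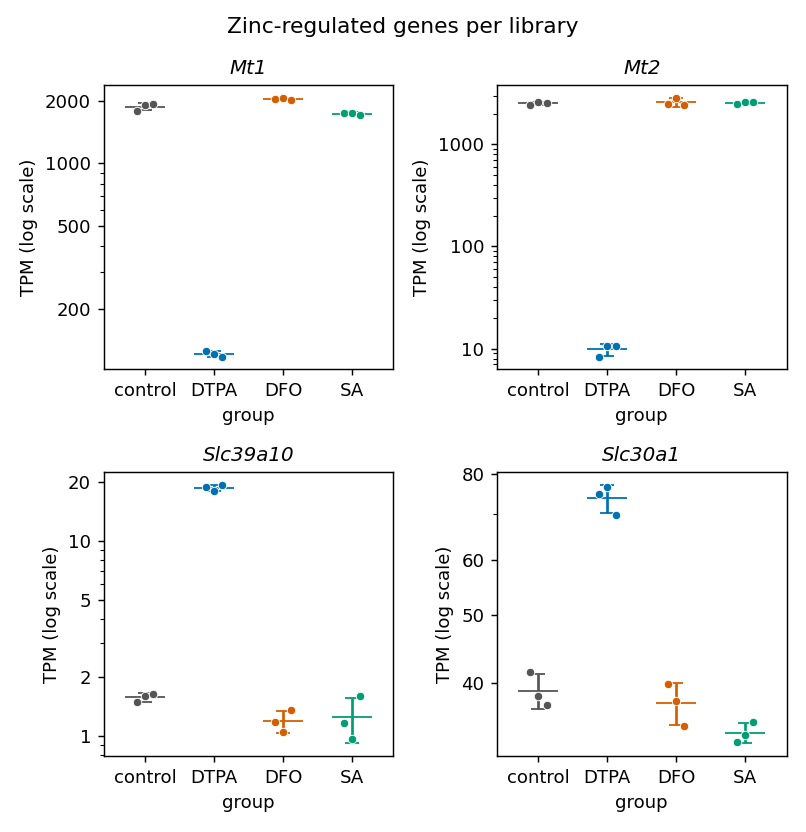
TPM per library (log axis) of Mt1, Mt2, Slc39a10 and Slc30a1 in the 4 groups. Points are the 3 libraries of a group, the long bar is their mean and the whiskers are 1 SD. Mt1 and Mt2 lie far lower with DTPA (means 122 and 9.82 TPM) than in any other group, and Slc39a10 (18.7 TPM) and Slc30a1 (73.7 TPM) lie higher.

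Embryonic globin transcripts, normally made by primitive red cells, rose with DTPA. Hbb-bh1 rose 104-fold, from 79.8 ± 0.647 to 8285 ± 365 TPM (log2 fold change 6.68, adjusted p = 1.95e-13). Hbb-y rose 43.6-fold, from 14.9 ± 1.40 to 650 ± 42.7 TPM, and the embryonic alpha-type gene Hba-x rose 8.64-fold to 67.9 ± 7.37 TPM. The adult gene Hbb-bs, chosen after its values were seen, rose by 0.45 in log2 to 26214 TPM. Hba-a1, an adult alpha globin, fell by 0.19, a call lost under median-of-ratios (adjusted p = 0.274) and trimmed-mean scaling (adjusted p = 0.162). Hba-a2, chosen after its values were seen, lay lower too, at 1887, 2064 and 2059 TPM with DTPA against 2959, 3762 and 3315 TPM in control. Hbb-bt varied so much between libraries (6002 ± 4560 TPM with DTPA against 2684 ± 587) that its difference did not pass (adjusted p = 0.163). Hbb-bs and Hbb-bt, like Hba-a1 and Hba-a2, are nearly identical copies, and how reads were split between them is uncertain. Of 10 measured globins, 5 rose, 4 fell and 1 did not pass. The list was higher than other genes by camera (adjusted p = 0.0333), with adjusted p = 0.168 with an estimated correlation and 0.0735 under median-of-ratios scaling. Hbb-bh1 lies on chromosome 7 from 103841637 to 103843164 and Hbb-y from 103851749 to 103853216.

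**Figure D2:**
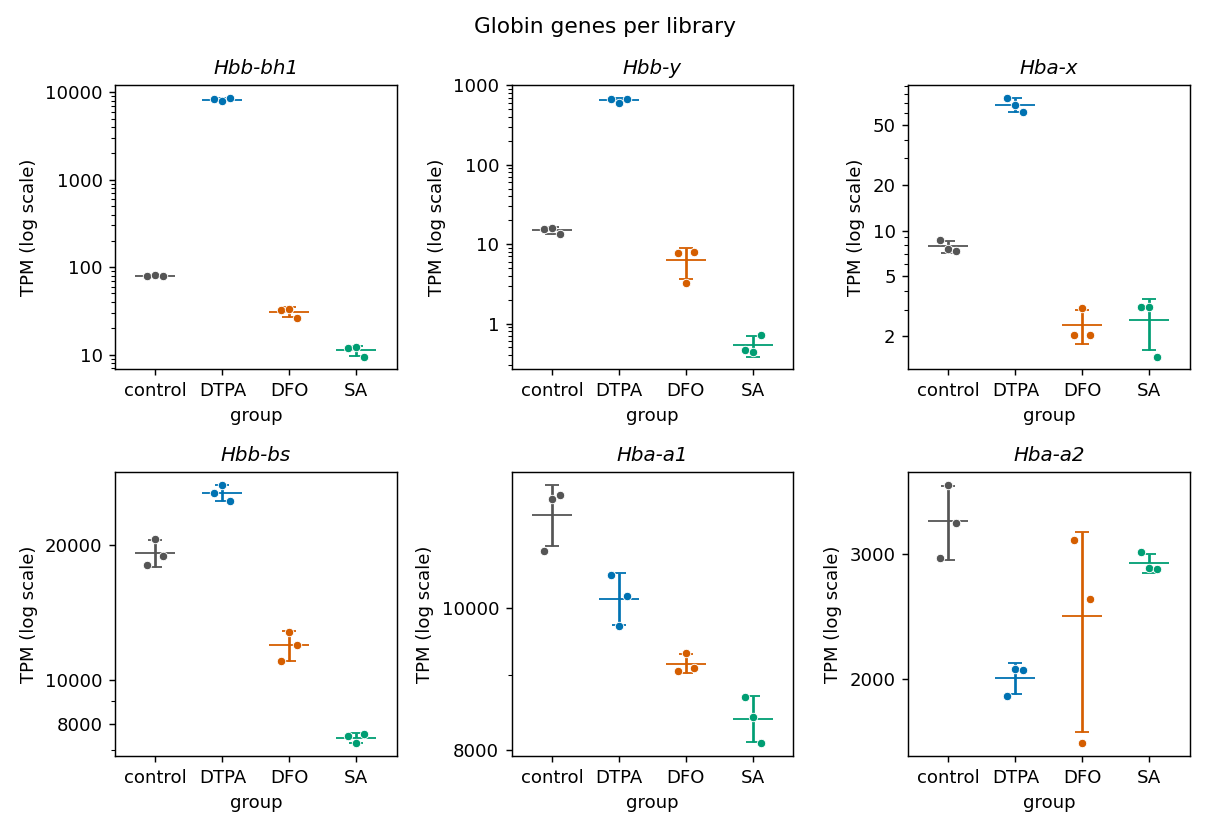
TPM per library (log axis) of 6 globin genes in the 4 groups. Points are the 3 libraries of a group, the long bar is their mean and the whiskers are 1 SD. Hbb-bh1 averaged 8285 TPM with DTPA, 79.8 in control, 30.6 with DFO and 11.2 with SA; Hba-a1 and Hba-a2 are near-identical copies and their split is uncertain.

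Genes of the dividing cell fell together. All 22 mitosis genes fell, with a median log2 fold change of -3.33 (camera adjusted p = 1.08e-14). Birc5, which encodes survivin of the chromosomal passenger complex, fell from 88.9 ± 5.06 to 4.04 ± 0.702 TPM, and the proliferation marker Mki67 fell from 217 ± 6.86 to 16.3 ± 0.585 TPM. All 24 genes of S phase and DNA replication fell, with a median of -1.70 (adjusted p = 1.2e-10). Rrm2, a subunit of ribonucleotide reductase, fell 15.9-fold to 6.51 ± 0.513 TPM and the replicative helicase gene Mcm5 fell 14.1-fold. All 21 measured cholesterol synthesis genes also fell (median -1.25, adjusted p = 2.22e-11), among them Fdps from 27.4 ± 0.525 to 5.61 ± 0.602 TPM and Hmgcs1, the first committed step toward mevalonate, from 469 ± 8.64 to 161 ± 3.97 TPM. These 3 lists gave adjusted p = 0.0376 each with an estimated correlation.

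Most erythroid maturation genes were lower with DTPA and progenitor genes were higher. Of 28 measured maturation genes, 20 fell, 6 rose and 2 did not pass. Slc4a1, the anion exchanger band 3 of the red cell membrane, fell from 718 ± 33.4 to 45.5 ± 3.32 TPM (log2 fold change -3.95, adjusted p = 6.96e-14). Rhd, a blood group membrane protein gene, and Tmod1, which caps actin filaments in the membrane skeleton, both fell to below 1 TPM (0.947 ± 0.626 and 0.953 ± 0.146). The rises included Gfi1b, a GATA1-induced repressor, from 276 ± 2.36 to 749 ± 26.0 TPM, and the blood group gene Kel from 11.1 ± 1.43 to 30.7 ± 1.41 TPM, both chosen after their values were seen. Gata1 reads, also chosen after they were seen, fell from 2501 ± 68.6 to 1058 ± 25.5 TPM (log2 fold change -1.24), and the values cannot separate the transgene from the disrupted locus. The list was lower than other genes (adjusted p = 0.00461), with adjusted p = 0.214 with an estimated correlation.

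Of 11 measured progenitor genes that GATA1 represses, 9 rose and 2 fell (median 0.96, adjusted p = 0.000506; 0.0376 with an estimated correlation). Kit, the stem cell factor receptor, rose 4.57-fold to 26.7 ± 0.735 TPM, the myeloid and lymphoid factor gene Spi1 rose 3.30-fold to 23.1 ± 1.62 TPM and the adhesion receptor gene Cd44 rose 3.11-fold to 8.80 ± 0.277 TPM. Markers of other blood cells moved beside them. Only 5 of 14 megakaryocyte markers were measured; 4 rose and 1 did not pass (adjusted p = 0.00389; 0.0376 with an estimated correlation), including the platelet integrin gene Itgb3 from 2.15 ± 0.189 to 17.0 ± 0.843 TPM and Gp1ba from 4.30 ± 0.463 to 18.5 ± 3.15 TPM. Of 22 mast cell and myeloid markers 2 were measured, and 1 rose (Hdc, histidine decarboxylase, 0.244 ± 0.0375 to 2.59 ± 0.369 TPM; list adjusted p = 0.261). Of 15 lymphoid markers the only one measured, Cd79a, rose from 0.569 ± 0.199 to 1.62 ± 0.365 TPM.

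Heme and iron genes moved both ways with DTPA. Alad, which encodes the zinc enzyme that forms porphobilinogen, fell 4.11-fold from 668 ± 14.4 to 162 ± 4.63 TPM (adjusted p = 9.41e-14). Alas2, the first and erythroid-specific step, rose from 2268 ± 17.9 to 3002 ± 10.3 TPM (log2 fold change 0.40, adjusted p = 8.26e-10). In the 15 heme synthesis genes 10 fell, 3 rose and 2 did not pass (adjusted p = 0.052). Of 16 measured genes of iron uptake and storage 5 rose, 7 fell and 4 did not pass, against 8 higher and 4 lower under median-of-ratios scaling. That list had a median of -0.051 and a mean of -0.114 while camera gave the direction up (adjusted p = 0.787). The mitochondrial iron importer gene Slc25a37 fell from 184 ± 5.82 to 87.8 ± 1.54 TPM and Aco1, the iron regulatory protein IRP1, rose from 117 ± 0.740 to 164 ± 2.25 TPM. Tfrc, the transferrin receptor, fell by 0.19 in log2 to 774 ± 21.4 TPM, a call lost under median-of-ratios scaling (-0.065, adjusted p = 0.0585). Alad lies on chromosome 4 from 62509169 to 62519918, Alas2 on chromosome X from 150547375 to 150570638 and Tfrc on chromosome 16 from 32608920 to 32632794.

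Stress and metabolic lists differed in direction. Of 24 measured ATF4 targets, genes of the integrated stress response, 19 fell, 1 rose and 4 did not pass (median -0.34, adjusted p = 0.000582; 0.0376 with an estimated correlation), with the asparagine synthetase gene Asns falling from 423 ± 4.66 to 204 ± 1.32 TPM and the mitochondrial serine enzyme gene Shmt2 falling 3.38-fold. Of 24 measured hypoxia-inducible genes 20 fell, 1 rose and 3 did not pass (median -1.13, adjusted p = 0.000425), but adjusted p = 0.318 with an estimated correlation; Ldha, lactate dehydrogenase A, fell from 1014 ± 141 to 153 ± 3.39 TPM and the angiogenic factor gene Vegfa from 8.02 ± 1.03 to 0.217 ± 0.0797 TPM. Of 19 measured p53 targets 11 rose, 5 fell and 3 did not pass (adjusted p = 0.00286; 0.0376 with an estimated correlation): Bbc3, the death-promoting gene PUMA, rose 2.02-fold to 194 ± 1.55 TPM, while Ckap2, a spindle gene, fell to 11.5 ± 0.715 TPM. Of 17 autophagy genes 11 rose, 2 fell and 4 did not pass (adjusted p = 0.00152; 0.0376 with an estimated correlation), led by the initiating kinase gene Ulk1 (38.2 ± 1.87 to 72.2 ± 1.99 TPM).

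In the 17 measured targets of BACH1 and NRF2, factors that respond to heme and oxidants, 12 fell, 4 rose and 1 did not pass (adjusted p = 0.052); Nqo1, a quinone reductase gene, fell 6.19-fold to 6.15 ± 1.21 TPM and Hmox1, heme oxygenase 1, fell 2.22-fold to 66.8 ± 4.62 TPM. Of 19 measured iron-sulfur cluster genes 12 fell, 3 rose and 4 did not pass (adjusted p = 0.208), against 6 higher and 7 lower under median-of-ratios scaling, with Bola3 falling 2.53-fold. Of 16 endoplasmic reticulum chaperone genes 14 fell and 2 rose (adjusted p = 0.0471), with adjusted p = 0.309 with an estimated correlation and 0.0735 under median-of-ratios scaling; the unfolded protein response factor gene Xbp1 fell from 150.4 ± 4.49 to 75.9 ± 0.796 TPM and Dnajb9 rose to 129 ± 5.76 TPM. Adjusted over the list alone, 7 maturation genes rose and 20 fell, and the counts of the other lists in this comparison were the same as over all genes. Under median-of-ratios scaling the counts with DTPA not given above became 5 higher and 8 lower for heme, 5 and 2 for globins, 7 and 18 for maturation, 2 and 16 for ATF4 targets, 3 and 18 for hypoxia-inducible genes, 5 and 10 for BACH1 and NRF2 targets, 12 and 4 for p53 targets, 2 and 10 for chaperones and 14 and 1 for autophagy, and the other lists kept theirs.

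Across all 11920 genes tested, 7811 differed between DTPA and control by limma, 2796 higher and 5015 lower, and 403 rose and 734 fell by at least 2-fold on the log2 scale. In 8290 of the 11920 genes (69.5%), 7648 of them called, the 3 treated libraries all lay above or all lay below the 3 controls, where chance gives 10%. Other genes with large rises were Alpk3, a kinase-like gene of heart muscle (2.85 ± 0.412 to 84.5 ± 2.15 TPM), the lysosomal gene Laptm5 (49.8 ± 2.00 to 490.0 ± 16.3 TPM) and the blood cell signalling gene Vav1 (17.2 ± 1.72 to 147 ± 2.79 TPM). Slc52a3, a riboflavin transporter gene, fell from 46.2 ± 7.55 to 1.22 ± 0.308 TPM. The split of directions moved with the scaling: median-of-ratios scaling, which raised the median of all genes by 0.11 in log2, gave 3784 higher and 3941 lower, and trimmed-mean scaling gave 3633 and 4103. Changes of about 0.1 in log2 in this comparison therefore have a direction only relative to the scaling.

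The comparison of DFO with control asked about low iron. Tfrc, whose mRNA is stabilised when iron is scarce, rose from 883 ± 24.1 to 1245 ± 48.8 TPM (log2 fold change 0.50, SE 0.0344, adjusted p = 1.94e-05), and the ferritin light chain gene Ftl1 fell from 25699 ± 1200 to 21607 ± 132 TPM (adjusted p = 0.000358; 0.0679 with no filter on low genes). The changes were small: the 1272 genes called, 1000 higher and 272 lower, had a median absolute log2 fold change of 0.194, and 11 rose and 11 fell by at least 2-fold. Of 16 measured iron genes 2 rose, 3 fell and 11 did not pass, and the list did not stand apart (adjusted p = 0.608; median 0.036 and mean 0.028 with direction down). Aco1 rose by 0.13 in log2, a call lost under median-of-ratios scaling (adjusted p = 0.0793) and trimmed-mean scaling (adjusted p = 0.0587). The ferritin heavy chain gene Fth1 fell from 2302 ± 54.7 to 2106 ± 50.6 TPM. Ftl1 also lay below control with DTPA (20923, 20612 and 20920 TPM) and with SA (18805, 19205 and 19143 TPM). Its fall was thus not particular to DFO.

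With DFO the globins and the lists of heme synthesis and maturation were lower than other genes. With TPM as deposited most members of the latter 2 were not called lower. Under median-of-ratios scaling 9 of 15 heme and 15 of 28 maturation genes were. Hbb-bh1 fell 2.61-fold to 30.6 ± 3.95 TPM, Hba-x fell 3.30-fold to 2.38 ± 0.600 TPM, and Hbb-bs fell from 19234 ± 1310 to 11975 ± 898 TPM (adjusted p = 7.10e-05). Hba-a1 fell from 11589 ± 563 to 9164 ± 138 TPM, while Hbb-bt did not pass (1314 ± 225 TPM, adjusted p = 0.276; 0.0216 from only the 6 libraries compared). Of 10 globins 6 fell and 4 did not pass (median -0.85, adjusted p = 2.33e-13; 0.00418 with an estimated correlation). Of 15 heme synthesis genes 6 fell, 1 rose and 8 did not pass (adjusted p = 2.10e-06; 0.0131 with an estimated correlation), with Alad at 574 ± 13.7 TPM (log2 fold change -0.22). Alas2 fell by 0.086 in log2 to 2137 ± 38.4 TPM (adjusted p = 0.00662; 0.0541 from only the 6 libraries compared). Of 28 maturation genes 12 fell, 1 rose and 15 did not pass (adjusted p = 6.16e-10; 0.018 with an estimated correlation), with Slc4a1 falling to 461 ± 12.5 TPM.

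Targets of BACH1 and NRF2 fell with DFO: 13 of 17 were lower, none was higher and 4 did not pass (median -0.21, adjusted p = 7.88e-22; 0.00454 with an estimated correlation). Nqo1 fell from 38.1 ± 2.80 to 21.1 ± 0.345 TPM, Srxn1, which repairs oxidised peroxiredoxin, from 71.7 ± 3.66 to 42.4 ± 0.784 TPM, and Hmox1 from 148 ± 0.718 to 99.9 ± 5.61 TPM. ATF4 targets rose: 15 of 24 were higher and 9 did not pass (median 0.18, adjusted p = 3.65e-08; 0.00454 with an estimated correlation), with Atf5 rising from 250.0 ± 3.53 to 346 ± 9.63 TPM and the amino acid transporter gene Slc7a5 from 731 ± 8.91 to 886 ± 20.1 TPM. Of 22 mitosis genes 20 fell and 2 did not pass (median -0.26, adjusted p = 2.19e-27; 0.00454 with an estimated correlation), Mki67 to 175 ± 5.88 TPM. Of 24 S phase genes 9 fell and 15 did not pass (adjusted p = 1.67e-17; 0.0131 with an estimated correlation), Rrm2 to 75.3 ± 2.05 TPM. Of 24 hypoxia-inducible genes 3 fell and 21 did not pass (adjusted p = 1.24e-07, but adjusted p = 0.215 with an estimated correlation); the glycolytic regulator gene Pfkfb4 fell to 166 ± 3.69 TPM.

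Few zinc genes passed with DFO. Slc39a10 (1.2 ± 0.153 TPM, adjusted p = 0.207), Mt2 (2583 ± 235 TPM, adjusted p = 0.84) and Slc30a1 (37.4 ± 2.59 TPM, adjusted p = 0.578) did not pass. Mt1 passed at 0.12 in log2 (2036 ± 21.2 TPM, adjusted p = 0.02), but not under median-of-ratios scaling (0.066, adjusted p = 0.315) nor without control replicate 1 (adjusted p = 0.0519), DFO replicate 1 (0.0556) or DFO replicate 2 (0.0691). Of 9 importers 1 rose, of 6 exporters none passed and of 3 metallothionein list members 1 rose (adjusted p = 0.639, 0.734 and 0.783). Kit rose from 5.83 ± 0.199 to 8.56 ± 0.190 TPM, the only one of 11 progenitor genes to pass, and the list did not stand apart (list adjusted p = 0.536 by camera). Of 19 p53 targets 7 rose and 12 did not pass (adjusted p = 0.0207, but adjusted p = 0.112 with an estimated correlation and 0.114 under median-of-ratios scaling), with Ccng1 at 399 ± 10.4 TPM against 345 ± 11.2.

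Of 16 chaperone genes 1 rose and 2 fell (adjusted p = 0.000796, but adjusted p = 0.112 with an estimated correlation), with Xbp1 falling to 137 ± 3.94 TPM (adjusted p = 0.0564 from only the 6 libraries compared). Of 21 cholesterol genes 2 rose (adjusted p = 0.827), among them Mvd (391 ± 4.97 TPM against 349 ± 8.11), whereas median-of-ratios scaling gave 1 higher and 4 lower (adjusted p = 0.0209, down). Of 19 iron-sulfur genes 3 rose and 1 fell (adjusted p = 0.379), with the co-chaperone gene Hscb rising to 128 ± 2.13 TPM. Of 17 autophagy genes 2 rose and 2 fell (adjusted p = 0.733). Of 5 megakaryocyte markers 2 rose (adjusted p = 0.517), with Nrgn at 399 ± 1.72 TPM, and neither the 2 myeloid markers (adjusted p = 0.734) nor the lymphoid one passed. The median and mean of the exporter, cholesterol, autophagy and myeloid lists were above 0 while camera gave the direction down, since the median of all genes was 0.045.

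Adjusted over the list alone, the counts with DFO rose to 5 higher and 4 lower for iron, 2 and 7 for heme, 0 and 7 for globins, 5 and 13 for maturation, 2 and 0 for progenitor genes, 8 and 0 for p53 targets, 0 and 17 for S phase, 0 and 22 for mitosis, 4 and 1 for iron-sulfur clusters, 1 and 4 for chaperones and 3 and 3 for autophagy, and were the same as over all genes for the others. Under median-of-ratios scaling, which lowered the median of all genes by 0.052, the counts became 0 higher and 0 lower for the metallothionein list, 1 and 4 for iron, 0 and 9 for heme, 0 and 15 for maturation, 11 and 1 for ATF4 targets, 0 and 4 for hypoxia-inducible genes, 4 and 0 for p53 targets, 0 and 17 for S phase, 0 and 21 for mitosis, 1 and 4 for cholesterol, 1 and 1 for iron-sulfur clusters, 0 and 5 for chaperones and 0 and 4 for autophagy, and the other lists kept theirs. The count of 1272 was 802 when only the 6 libraries compared were fitted, and 844, 847 and 840 without DFO replicates 1, 2 and 3. The split of 1000 higher and 272 lower became 420 and 654 under median-of-ratios scaling, 420 and 636 under trimmed-mean scaling and 725 and 333 with the globin genes removed. At p below 0.05 without adjustment 3025 genes passed.

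The comparison of SA with control asked about low protoporphyrin through ALAD inhibition. ATF4 targets rose with SA: 20 of 24 were higher, none was lower and 4 did not pass (median 0.47, adjusted p = 2.41e-16; 0.00132 with an estimated correlation). Trib3, a pseudokinase gene induced by ATF4, rose from 11.0 ± 1.60 to 26.1 ± 0.731 TPM (log2 fold change 1.18, SE 0.0975, adjusted p = 9.41e-06), Atf5 rose 2.07-fold to 518 ± 11.9 TPM and the transcription factor gene Cebpg rose 1.70-fold to 52.8 ± 1.54 TPM. In all 2643 genes differed, 1839 higher and 804 lower, with 16 rising and 25 falling by at least 2-fold. Other large rises were Soat2, which esterifies cholesterol (18.6 ± 1.80 to 38.6 ± 3.51 TPM), Hsd17b14 (12.6 ± 1.63 to 26.1 ± 1.03 TPM) and Hoxc5 (37.6 ± 1.10 to 71.7 ± 2.66 TPM).

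Globins and the targets of BACH1 and NRF2 fell with SA. Hbb-y fell 27.5-fold as a ratio of means, to 0.543 ± 0.158 TPM, a level that rests on few reads (log2 fold change -3.37). Hbb-bh1 fell 7.16-fold to 11.2 ± 1.46 TPM (log2 fold change -2.74, adjusted p = 3.14e-08) and Hbb-bs fell from 19234 ± 1310 to 7452 ± 189 TPM. Hba-a1 fell to 8399 ± 305 TPM and Hbb-bt did not pass (1698 ± 1340 TPM, adjusted p = 0.263). Of 10 globins 5 fell and 5 did not pass (median -0.88, adjusted p = 7.88e-10; 0.00323 with an estimated correlation). Of 17 BACH1 and NRF2 targets 15 fell and 2 did not pass (median -0.54, adjusted p = 2.58e-25; 0.00323 with an estimated correlation). Hmox1, a heme-degrading enzyme gene repressed by BACH1, fell from 148 ± 0.718 to 57.1 ± 3.18 TPM (log2 fold change -1.36, adjusted p = 5.90e-08), Srxn1 fell to 30.7 ± 1.77 TPM and the malic enzyme gene Me1 fell 2.38-fold to 6.61 ± 0.435 TPM. Hmox1 lies on chromosome 8 from 75093621 to 75100589.

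All cholesterol synthesis genes and some iron genes were also lower. Tfrc fell from 883 ± 24.1 to 626 ± 20.9 TPM (log2 fold change -0.50, adjusted p = 2.93e-06) and Ftl1 fell to 19051 ± 215 TPM. Of 16 iron genes 6 fell, 3 rose and 7 did not pass (adjusted p = 0.000637, but adjusted p = 0.108 with an estimated correlation). All 21 cholesterol synthesis genes fell (median -0.29, adjusted p = 4.11e-26; 0.00323 with an estimated correlation), Idi1 from 164.0 ± 3.11 to 111 ± 4.90 TPM and Hmgcs1 to 348 ± 10.2 TPM. Of 15 heme synthesis genes 6 fell, 4 rose and 5 did not pass (adjusted p = 0.157; 0.0274 under median-of-ratios scaling), with a median of -0.037, a mean of 0.019 and camera direction down. Alas1, the housekeeping form of the first enzyme, rose to 4.27 ± 0.461 TPM and Ppox to 250.0 ± 3.69 TPM. Alas2 fell by 0.068 in log2 to 2164 ± 12.9 TPM (adjusted p = 0.011; 0.0658 with no filter), and Alad, the inhibited enzyme, had a log2 fold change of -0.084 (630.0 ± 6.92 TPM, adjusted p = 0.0367) whose call was lost without control replicate 1 (adjusted p = 0.0858), control replicate 3 (0.128), SA replicate 1 (0.111), SA replicate 2 (0.0807) or SA replicate 3 (0.0631).

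**Figure D3:**
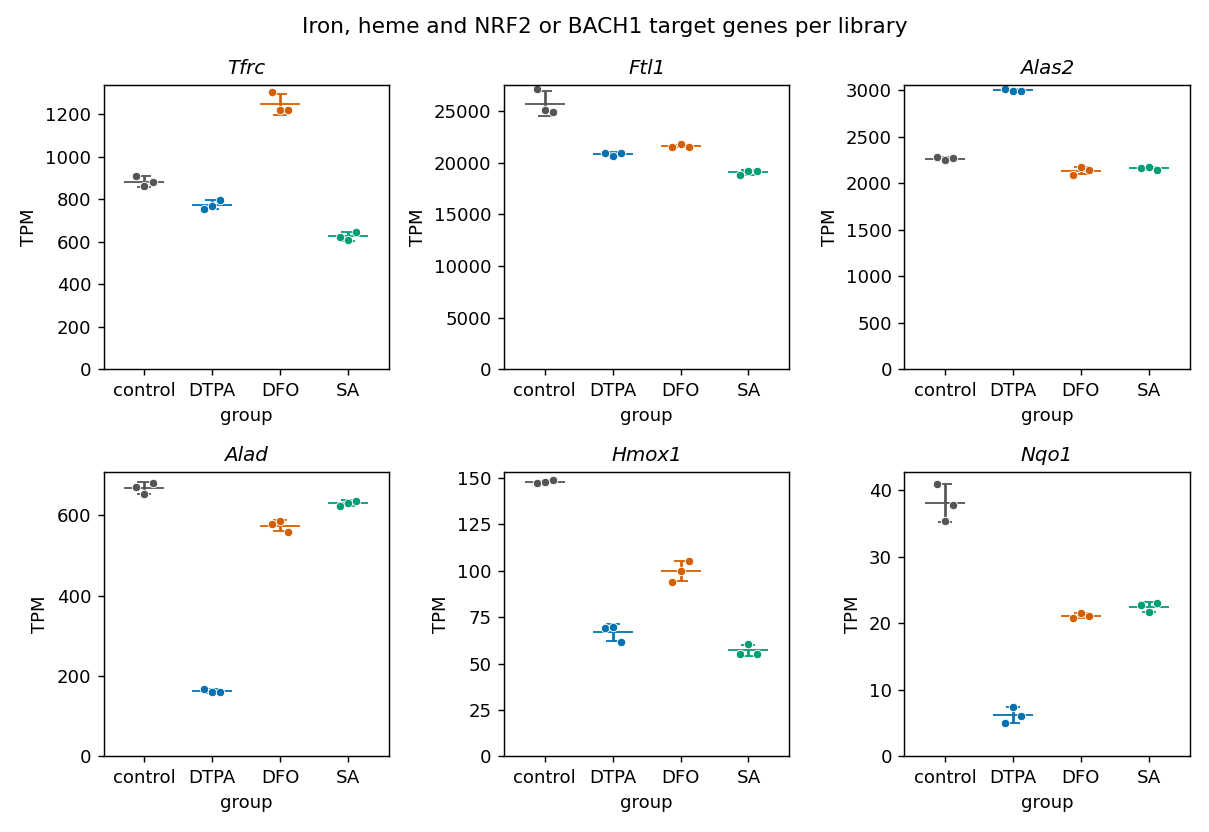
TPM per library (linear axes from 0) of Tfrc, Ftl1, Alas2, Alad, Hmox1 and Nqo1 in the 4 groups. Points are the 3 libraries of a group, the long bar is their mean and the whiskers are 1 SD. Tfrc averaged 1245 TPM with DFO and 626 with SA against 883 in control, Alad averaged 162 TPM with DTPA against 668, and Hmox1 and Nqo1 lay below control in every treatment.

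Of 28 maturation genes 9 fell, 3 rose and 16 did not pass with SA (adjusted p = 0.00258, but adjusted p = 0.191 with an estimated correlation), with Slc4a1 falling from 718 ± 33.4 to 520 ± 1.14 TPM and the blood group gene Icam4 rising to 192 ± 4.44 TPM. Of 11 progenitor genes 3 rose and 1 fell (adjusted p = 0.638), with Kit at 9.34 ± 0.302 TPM and Gata2, a progenitor GATA factor, at 35.9 ± 1.5 TPM against 26.6 ± 1.29. Of 19 p53 targets 9 fell, 2 rose and 8 did not pass (median -0.094, adjusted p = 0.000115; 0.0211 with an estimated correlation), the cell cycle inhibitor gene Cdkn1a falling from 196 ± 4.79 to 147 ± 5.41 TPM. Of 24 S phase genes 17 fell and 7 did not pass (median -0.23, adjusted p = 2.37e-12; 0.0355 with an estimated correlation), Mcm5 from 119 ± 3.76 to 77.2 ± 2.77 TPM. Of 22 mitosis genes 3 fell and 19 did not pass (adjusted p = 0.000314, but adjusted p = 0.191 with an estimated correlation), Mki67 to 194 ± 5.51 TPM. Of 24 hypoxia-inducible genes 12 fell, 1 rose and 11 did not pass (adjusted p = 3.42e-07, but adjusted p = 0.193 with an estimated correlation), with Vegfa at 4.18 ± 0.859 TPM and Bnip3, a mitophagy receptor gene, at 173 ± 20.5 TPM against 253 ± 31.5.

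Of 16 chaperone genes 7 fell, 2 rose and 7 did not pass (adjusted p = 0.00161, but adjusted p = 0.157 with an estimated correlation), with Pdia6 falling to 48.6 ± 1.13 TPM and Herpud1 rising to 70.5 ± 4.66 TPM. Of 19 iron-sulfur genes 6 rose and 1 fell (adjusted p = 0.0738), Nfu1 rising to 34.8 ± 0.550 TPM. Of 17 autophagy genes 3 rose and 2 fell (adjusted p = 0.539, median 0.022 and mean 0.006 with direction down), the receptor gene Sqstm1 falling to 264 ± 4.87 TPM. Of 9 importers 2 rose (adjusted p = 0.931, median 0.033 and mean 0.017 with direction down), and no importer passed under median-of-ratios scaling. Slc39a10 (1.25 ± 0.327 TPM, adjusted p = 0.205) and Mt2 (2556 ± 68.2 TPM, adjusted p = 0.888) did not pass. Of 6 exporters 2 fell (adjusted p = 0.211); Slc30a1 passed at -0.196 in log2 (adjusted p = 0.0295), a call lost without control replicate 1 (adjusted p = 0.104), control replicate 2 (0.055), SA replicate 1 (0.0938) or SA replicate 2 (0.0781).

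Mt1, the 1 of 3 metallothionein list members to fall with SA (list adjusted p = 0.265), passed at -0.113 (1729 ± 26.9 TPM, adjusted p = 0.0157), a call lost without control replicate 2 (adjusted p = 0.0559), control replicate 3 (0.0632) or SA replicate 3 (0.0604). Of 5 megakaryocyte markers 1 rose (Nrgn, 411 ± 10.0 TPM; list adjusted p = 0.66), and neither the 2 myeloid markers (adjusted p = 0.638) nor the lymphoid one passed. Adjusted over the list alone, the counts with SA were 1 higher and 2 lower for exporters, 3 and 7 for iron, 0 and 6 for globins, 4 and 9 for maturation, 21 and 0 for ATF4 targets, 1 and 13 for hypoxia-inducible genes, 3 and 10 for p53 targets, 1 and 18 for S phase, 7 and 1 for iron-sulfur clusters, 3 and 9 for chaperones, 5 and 2 for autophagy and 1 and 1 for megakaryocyte markers, and the same as over all genes for the others. Under median-of-ratios scaling they were 0 higher and 0 lower for importers, 0 and 3 for exporters, 1 and 8 for iron, 3 and 8 for heme, 3 and 13 for maturation, 2 and 2 for progenitor genes, 1 and 13 for hypoxia-inducible genes, 0 and 17 for BACH1 and NRF2 targets, 2 and 12 for p53 targets, 0 and 18 for S phase, 0 and 9 for mitosis, 4 and 2 for iron-sulfur clusters, 2 and 10 for chaperones, 1 and 5 for autophagy and 1 and 1 for megakaryocyte markers, and as before for the other lists. The split of 1839 higher and 804 lower became 1108 and 1663 under median-of-ratios scaling, 1140 and 1601 under trimmed-mean scaling and 1485 and 1046 with the globin genes removed.

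**Figure D4:**
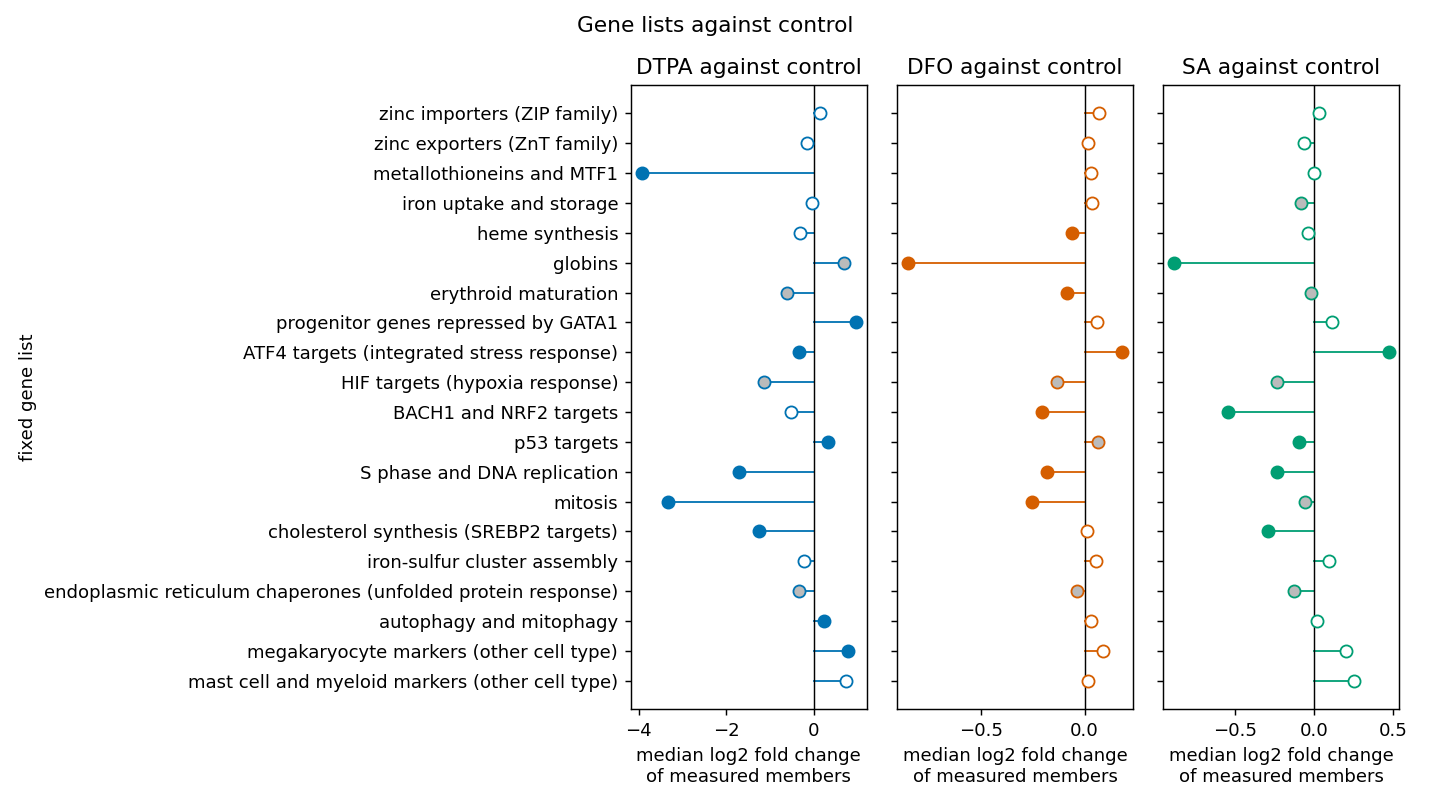
Median log2 fold change (x axis, log2 units of TPM + 1, a different range in each panel) of the measured members of 20 gene lists (y axis) for DTPA, DFO and SA against control. Coloured points passed camera with the preset and with an estimated inter-gene correlation, grey points passed only with the preset, and open points passed neither. Mitosis had a median of -3.33 with DTPA and globins of -0.85 with DFO and -0.88 with SA.

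The treatments were then compared with each other, which asks how the responses to the 3 agents differ. The RNA values do not measure zinc, iron or protoporphyrin, so the differences belong to the agents as given. DTPA differed from DFO in 7858 genes (2330 higher with DTPA, 5528 lower) and from SA in 7994 (2395 higher, 5599 lower). Hbb-bh1 was 270-fold higher with DTPA than with DFO and 743-fold higher than with SA (adjusted p = 8.31e-14 and 1.89e-14). Mt2 was 263-fold lower with DTPA than with DFO and 260-fold lower than with SA, and Slc39a10 was 15.6-fold and 15.0-fold higher. Mt1 was lower by 4.05 and 3.81 in log2. Slc30a1 was higher with DTPA by 0.96 and 1.10, and Alad lower, with log2 differences of -1.81 and -1.95. Hmox1 was lower with DTPA than with DFO (-0.57) and higher than with SA (0.22, adjusted p = 0.00368). Hba-a1 was higher with DTPA than with DFO by 0.15 (adjusted p = 0.0593 with no filter) and than with SA by 0.27, and Hbb-bt by 1.94 and 1.85 (adjusted p = 0.00829 and 0.0106) despite its SD of 4560 TPM with DTPA. Median-of-ratios scaling shifted the median of all genes by 0.16 in both comparisons and gave 3732 higher and 3860 lower against DFO and 3763 and 3933 against SA; trimmed-mean scaling gave 3559 and 4027, and 3592 and 4118.

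DFO and SA differed in 1612 genes, 860 higher with DFO and 752 lower. Tfrc was 1.99-fold higher with DFO (1245 ± 48.8 against 626 ± 20.9 TPM, log2 difference 0.99, adjusted p = 1.34e-07) and Hmox1 was 1.75-fold higher (adjusted p = 5.93e-06). Hbb-bh1 was 2.75-fold higher, and Hbb-y was 11.6-fold higher as a ratio over 0.543 TPM with SA (log2 difference 2.17). Trib3 was 1.99-fold lower with DFO (adjusted p = 9.03e-05) and the growth arrest gene Gadd45b 2.03-fold lower (5.63 ± 0.618 against 11.4 ± 1.04 TPM). Alad was lower with DFO by 0.13 in log2 and Mt1 higher by 0.24 (adjusted p = 0.00533 and 0.000294). Slc39a10, Mt2, Slc30a1, Alas2, Hba-a1 and Hbb-bt did not pass (adjusted p = 0.919, 0.951, 0.143, 0.509, 0.0614 and 0.943), though Hba-a1 passed with the filter of 5 TPM (adjusted p = 0.045) and from only the 6 libraries compared (0.0407). In a list test added after the comparisons with control, all 21 cholesterol genes were higher with DFO than with SA (median 0.31, adjusted p = 5.13e-27; 0.00522 with an estimated correlation).

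With TPM as deposited, many genes were called in the same direction by more than 1 treatment. Overlaps were not counted under other scalings. Median-of-ratios and trimmed-mean scaling each called 420 genes higher with DFO, fewer than the 620 and 567 shared higher genes below, so these counts depend on the scaling. DFO and SA shared 620 higher genes, where independent lists would share 154, and 162 lower genes, where they would share 18.3; of these, 161 and 71 also differed between DFO and SA directly. Another 28 genes were higher with DFO and lower with SA and 8 the reverse. DTPA and DFO shared 567 higher (235 if independent) and 217 lower (114), of which 414 and 196 also differed directly. DTPA and SA shared 720 higher (431) and 521 lower (338), of which 476 and 433 differed directly. In opposite directions, 35 genes were higher with DTPA and lower with DFO (63.8 if independent) and 283 the reverse (421). Against SA these counts were 184 (189) and 717 (774). Unchanged groups simulated against 3 common controls shared 0 calls in each pair. The simulation leaves out the effects and the independent lists leave out the common controls, so neither difference measures a shared effect. Fold changes across the 11920 genes, which are not independent replicates, correlated with Pearson's r of 0.305 for DTPA and DFO, 0.225 for DTPA and SA and 0.514 for DFO and SA. Unchanged groups simulated against 3 shared controls gave 0.501. Those groups held no effects, so 0.501 follows from the sharing alone. It is not a baseline for the observed r, whose spread includes effects. The covariances were 0.0455, 0.0388 and 0.0295 against 0.0185 in the simulation, differences of 0.0271, 0.0203 and 0.011. The 3 controls are too few to be divided between the comparisons, and part of each overlap may come from the shared controls.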

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

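The list tests between treatments, and the tests of other cell types, shared controls, scaling and DFO-specific target activity below, were chosen only after the result was seen. Each difference in this paragraph came from the direct limma contrast between treatments and joined genes or lists with opposite signs against control; the changes of Mt1 with DFO and SA, of Slc30a1 with SA, of Tfrc with DTPA, of Alas2 with DFO and SA, of the globin list with DTPA and of the p53 targets with DFO against control lost their call in some settings given in the report. Mt1 had a log2 difference of -4.05 between DTPA and DFO and of 0.236 between DFO and SA. Tfrc differed by -0.686 between DTPA and DFO and by 0.991 between DFO and SA. Alas2 was higher with DTPA than with DFO by 0.491 and than with SA by 0.472, and Slc30a1 was higher with DTPA than with SA by 1.10. By camera, the globin list had a median difference of 1.54 between DTPA and DFO (adjusted p = 0.000104; 0.0272 with an estimated correlation) and of 1.83 between DTPA and SA (0.000133; 0.0284). The ATF4 targets had medians of -0.502 (adjusted p = 1.37e-05; 0.0272 with an estimated correlation) and -0.883 for the same pairs. The p53 targets were higher with DTPA than with SA (median 0.487, adjusted p = 3.96e-05; 0.0175 with an estimated correlation) and higher with DFO than with SA (0.227, adjusted p = 8.55e-08; 0.00563).

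The 6 libraries of a comparison make 10 splits into 3 and 3, too few for a share under 0.05. In fits of those 6 libraries, 1 of the 10 splits, the real one, called 7633 genes for DTPA, 802 for DFO, 2212 for SA, 7689 between DTPA and DFO, 7821 between DTPA and SA and 1288 between DFO and SA, and the highest other split called 1, 1, 3, 1, 1 and 2.

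With DTPA more genes were called lower than higher. Transcript length as the whole cause is argued against: the share called higher was 38.8% in the shortest of 4 equal groups by exon length and 35.6%, 34.9% and 34.9% in the others. A few gene classes taking a larger part of a fixed total may account for much of it: without the 142 globin, ribosomal protein and mitochondrially encoded genes 47.7% of called genes were higher (3634 higher and 3992 lower), against 35.8% with them. A biological excess of falls beyond this stays open.

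Progenitor and megakaryocyte genes were higher and maturation genes lower with DTPA, the maturation list without passing with an estimated correlation (adjusted p = 0.214). Only cells rich in a chosen set of transcripts are argued against as a source. Among these transcripts, abundant in megakaryocytes, myeloid, mast or lymphoid cells, the highest mean with DTPA was 1.19 TPM (Itga2b, 1.04 in control). Pf4 was at 0.374 TPM (0 in control), and Ppbp, Mpo, Lyz2, S100a8, S100a9, Mcpt8 and Cd79b were listed at 0. The set came from the fixed marker lists, so its low values were already known. It left out the megakaryocyte markers Itgb3, Gp1ba, Gp9 and Nrgn, the mast cell and myeloid marker Hdc and the lymphoid marker Cd79a. These were all the called members of the marker lists, and all of them rose. Cells without the chosen transcripts are therefore not covered. Held-back maturation may account for the pattern but stays undecided. The 23 erythroid genes outside the fixed lists had a median -0.218 from that of all genes. They did not pass camera (p = 0.127, or 0.256 with an estimated correlation). Gata1 reads, themselves a member of the maturation list, also fell with DTPA, as given above. Whether that fall bears on these genes was not tested.

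BACH1 and NRF2 targets were lower with DFO and with SA. The scaling is argued against as the whole cause, since 1 factor per library moves all genes alike and the list lay -0.252 from the median of all genes with DFO and -0.591 with SA (adjusted p = 0.00454 and 0.00323 with an estimated correlation). Shared control libraries are argued against as the whole cause of both falls, since the list differed between DFO and SA directly by a median of 0.247 beyond all genes (adjusted p = 1.28e-14; 0.0131 with an estimated correlation). For the fall with DFO alone, chance values of the controls had no separate test. The error of the list test includes their spread (camera p = 0.000709 with an estimated correlation). That is the same test that called the fall, so it adds no evidence and this explanation stays open. A shift common to all 3 controls was not tested and stays open. Lower activity of these targets in general is a candidate explanation with SA, where 14 measured targets outside the fixed lists lay -0.123 from all genes (0 higher, 6 lower, camera p = 9.15e-07; 0.00911 with an estimated correlation). With DFO the same targets lay at 0.0474 from all genes, 1 higher and 3 lower, with camera direction down and past no threshold. The rule written before for SA counts a median at or above that of all genes against the explanation, and by it this median would count against; the looser bounds used with DFO were written after its value was seen. The explanation is left undecided there, since members went both ways about a median near 0.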

How the results depend on the processing

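Voom on recovered reads, the protein-coding rescaling and correlations without single control libraries were chosen only after the result was seen. Of 159 named gene results, 145 kept their direction and side of the threshold in every alternative run on them; of 2515 values, 33 were no longer past it, 3 newly passed and 0 reversed, and leaving out a library gave 15 of the 33. Asking for an absolute log2 fold change of at least 1 left 1137 genes for DTPA, 22 for DFO, 41 for SA, 1077 between DTPA and DFO, 1175 between DTPA and SA and 30 between DFO and SA, by construction. Only the 6 libraries compared gave 802 genes for DFO, with fewer samples behind the spread, and leaving out single libraries gave 840 to 960, of which the 844, 847 and 840 without a DFO library moved by over 1.5 times. The remaining 104 of 114 alternative totals, those without a control library included, stayed within 1.5 times. The correlation of DTPA with DFO was 0.342 with the filter of 5 TPM; that of DTPA with SA was 0.286 with a pseudocount of 0.1, 0.197 with 5, 0.200 with the filter of 5 TPM and 0.257 without globin genes; the cause was not tested. Leaving out single libraries gave 0.274 to 0.345, 0.206 to 0.272 and, for DFO with SA, 0.462 to 0.596. With an estimated correlation 22 list results passed, against 34 with the preset. The fry test turned zinc exporters (adjusted p = 0.000984) and iron uptake and storage (0.00228) with DTPA to down; it does not compare a list with other genes. Of 240 list values, 206 kept their call, 17 lost it and 15 gained it. The replicate numbers did not pair the samples (correlations of deviations between -0.043 and 0.0534 over 18 pairs); the replicate block gave 1058 genes for DFO and among named genes ended only the call of Alad with SA. Robust empirical Bayes, voom (8001, 1457 and 3058 genes for DTPA, DFO and SA) and the protein-coding rescaling moved no total by over 1.5 times, though voom called 498 genes lower with DFO against 272. DESeq2 size factors, planned for counts, were not run, since the values are TPM. At a step of 0.124 to 0.160 TPM for 1 read per kilobase, differences of genes near 1 TPM can rest on few reads, the fewer the shorter the exons.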

Other observations

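The gene families here were chosen after the data were seen, and all of their tests with them. Cytosolic ribosomal protein genes, 85 of them measured, were higher in every treatment: 77 rose and 2 fell with DTPA (median log2 fold change 0.51), 62 rose with DFO (0.14) and 75 rose and 1 fell with SA (0.24). Under median-of-ratios scaling the counts were 79 and 0, 32 and 0, and 66 and 1. Camera gave adjusted p = 5.82e-30, 5.83e-29 and 1.90e-33, with adjusted p = 0.0504, 0.0402 and 0.0334 with an estimated correlation. Of 35 proteasome genes 34 fell and 1 rose with DTPA (median -0.46, adjusted p = 2.55e-08; 0.0514 with an estimated correlation), 6 fell and 1 rose with DFO (adjusted p = 2.26e-09; 0.0402 with an estimated correlation) and 12 fell with SA (adjusted p = 5.54e-10; 0.0334 with an estimated correlation). Under median-of-ratios scaling 29 fell and 1 rose with DTPA, 17 fell with DFO and 26 fell with SA.

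Of 36 measured complex I genes of the respiratory chain 29 fell and 1 rose with DTPA (median -0.49, adjusted p = 2.16e-05; 0.0504 with an estimated correlation). With DFO 2 rose and with SA 6 rose (adjusted p = 0.953 and 0.97), counts that became 1 fall and 5 falls under median-of-ratios scaling. Of 12 tubulin genes 5 rose and 7 fell with DTPA (median -0.45 but camera direction up, adjusted p = 0.991), 5 fell and 1 rose with DFO (median -0.14, adjusted p = 2.26e-09; 0.0149 with an estimated correlation) and 7 fell with SA (median -0.23, adjusted p = 5.54e-10; 0.0126). Under median-of-ratios scaling 8 tubulin genes fell and 1 rose with DFO, and 9 fell with SA.

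Of 23 measured mitochondrially encoded genes 9 rose with DTPA (adjusted p = 0.0028, but adjusted p = 0.0777 with an estimated correlation), 2 rose with DFO (camera direction down, adjusted p = 0.0153, but adjusted p = 0.144 with an estimated correlation) and 2 rose with SA (adjusted p = 0.881). Under median-of-ratios scaling 13 rose with DTPA, and 1 rose and 2 fell with DFO and with SA. Of 260 genes named Zfp 82 rose and 87 fell with DTPA (adjusted p = 0.102), 12 rose and 1 fell with DFO (0.193) and 55 rose and 6 fell with SA (adjusted p = 0.00169, but adjusted p = 0.188 with an estimated correlation). Under median-of-ratios scaling the counts were 108 and 64, 2 and 4, and 25 and 10. Complex I genes with DTPA became 3 higher and 25 lower.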
